A study of Mus musculus with 7 samples.

How the data were processed

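ILC2s from Gfi1 wild-type and knockout mice were profiled on 7 two-colour Agilent mouse gene expression arrays, 4 wild type and 3 knockout. Per the labels, the red dye (Cy5) carried the ILC2 sample and the green dye (Cy3) a commercial universal mouse reference RNA on every array, with no dye swap, so a dye effect on a gene is the same on all arrays and drops out of differences between groups. Per the labels' protocols, culture used 50 ng/ml IL-2, 10 ng/ml IL-7 and 50 ng/ml IL-25. The deposited scanner files give intensity values per spot on a linear scale, written by Agilent Feature Extraction version 11.0.1.1 per the file headers, while the submitters' processing notes name version 10.7.3.1. They also hold a log10 ratio of red over green per spot, background-subtracted and dye-normalized by the scanner software per the file headers. The deposited series value table holds log2 ratios: each value equalled the log10 ratio turned to log2 to within 0.001, so its scale and direction are known and no further centring was found. Its column medians ran from 0.163 to 0.254.

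The design fixed before the data were examined named mean signals. The files used here hold median signals, so median foreground and median local background were used. Spots were corrected with normexp (offset 50), normalized within each array by loess with control spots at weight 0, and spots of one probe were averaged, in limma 3.58.1 under R 4.3.3. Figures were drawn with matplotlib 3.10.9. Control spots were left out, as were spots with outlier flags (2597 over the 7 arrays), and no tested gene had a saturated signal in the sample channel.

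The handling of outlier flags was chosen after seeing the data, and the counts of called genes under 3 handlings were seen before it was settled. With feature flags alone, applied after the background model, 1780 genes were called (755 higher, 1025 lower). On wild-type array 4 the model then fitted a background of -199, against -14.0 to -4.18 on the other arrays, because of 3 spots whose local background far exceeded their signal. With all flagged spots left out before the model, background population outliers included, 1824 genes were called (797 higher, 1027 lower), but many tested genes lost a value, which the set tests cannot take. The handling used here leaves out feature outliers and spots of non-uniform local background before the model. It gave 1908 calls, the most of the 3, and left 88 tested genes with a missing value.

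The array holds 39429 probes after controls. The files used here hold no gene names, so probes were named through their accessions in a table of RefSeq genes (assembly GRCm38.p6): 26581 probes had 1 gene, none had several and 12848 stayed unnamed and were tested under their accession. The array design uses build mm9, so no coordinates are given, and the table served only for names and for which genes lie near each other. Genes were tested where the sample channel was well above background on at least 3 arrays and each group had at least 2 values. This left 30293 probes and 25347 genes, 16690 of them with a symbol. The probe with the highest mean sample-channel signal stood for a gene. Of 427 called genes with several tested probes, 2 had another probe called in the opposite direction.

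Groups were compared with lmFit and eBayes, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05, and no block. Fold changes are 2 to the power of the log2 difference. The normexp offset draws dim probes' ratios towards 0. Where a gene was well above background on no array of a group, the fold is a lower bound from the sample channel after loess and Aquantile: the bright group's mean against, per array, the higher of the gene's own signal and the lowest signal above background. Without a dye swap this bound is open to dye bias. Of the tested genes, 23 were above background on no wild-type array and 14 on no knockout array.

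The 29 gene lists were fixed before the data were examined. They were tested with camera on moderated statistics with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Named genes were Gfi1, the 12 largest rises and 12 largest falls among called genes with a symbol whose groups did not overlap, up to 4 members with the smallest p of each list described, and 23 genes fixed by name, all by a rule set beforehand. Some of the genes so chosen are left out of the text. Calls near Gfi1 were compared with Fisher's exact test. Alternatives covered the background correction, normalization within and between arrays, the series value table, the sample channel alone, filters, probe choice, variance models, slide, replicate number, each array left out and a minimum change. Alternatives added after seeing the data were the 2 other flag handlings, an Xist minus Ddx3y covariate and leaving out the arrays in doubt. All scans were made on 1 day with 1 scan time per slide, so scan and slide are the same batch. Knockout array 3 had a scanner quality result asking for evaluation, and the other 6 were in range. Whether equal replicate numbers pair the samples was checked from correlations of deviations, and they were not treated as pairs.

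The steps were tested on simulated data for the comparison of knockout with wild type, over 25347 genes with the real means and spreads and 200 changed genes. At log2 changes of 0.5, 1 and 2 the test recovered 40.3%, 91.0% and 98.5% of the changed genes, with 3 of the 156 calls among the unchanged ones. A draw with the genes in another order recovered somewhat more, so these shares vary with the draw. With no gene changed there were 0 calls, and a single list shifted by -0.6 was the 1 list to pass. The simulation drew genes independently, so it does not test the set test against correlated genes.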

Results

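Gene expression was measured in group 2 innate lymphoid cells (ILC2s), lymphocytes without antigen receptors that make type 2 cytokines such as IL-5 and IL-13. The cells came from wild-type mice or from mice homozygous for a Gfi1 allele in which a GFP cassette had been inserted, which removes the function of this transcriptional repressor while reporting the activity of its promoter. Mice received IL-25 for 4 days, and ILC2s were sorted from the mesenteric lymph nodes on day 5 and cultured for 6 days with IL-2, IL-7 and IL-25. Each wild-type sample pooled 3 mice and each knockout sample pooled 6. There were 4 wild-type and 3 knockout arrays, each holding 1 sample in the red channel and a common mouse reference RNA in the green channel, so every value below is a log2 ratio of sample over reference, unless the sample channel is named, and every difference is knockout minus wild type. The labels give each sample its own pool of mice, and the small number of arrays limits the precision. Between 67.4% and 80.9% of probes lay well above background in the sample channel of an array. Log ratios correlated at 0.979 to 0.989 among wild-type arrays, at 0.969 to 0.980 among knockout arrays and at 0.942 to 0.969 between the groups, over genes, which are not independent replicates. The first principal component held 52.0% of the variance and separated the groups.

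The Gfi1 transcript was examined first. Its single probe read 4.28 ± 0.02 (SD, n = 3) on the arrays labelled Gfi1 knockout and 2.02 ± 0.23 (SD, n = 4) on the wild-type arrays, a 4.77-fold higher level in the knockout (log2 difference 2.25, limma adjusted p = 1.63e-05), with all 3 knockout arrays above all 4 wild-type arrays. The difference was 2.33 within slide 1 and 2.37 within slide 2, and 2.35 with slide as a block (adjusted p = 0.0014). The allele keeps the promoter active, and the position of the probe relative to the inserted cassette is not known here. The probe therefore checks no label, and the directions below rest on the labels alone.

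The largest rises in knockout ILC2s by fold were in Il17a, Ccr10, Urah and Il17f. Il17a and Il17f, the cytokines that define type 17 lymphocytes, were 49.2-fold and 21.9-fold higher on the arrays labelled knockout (log2 differences 5.62 ± 0.28 and 4.45 ± 0.12, SE; adjusted p = 1.4e-05 and 2.08e-07). The Il17f signal also differed in the reference channel, by 1.13, so that its rise in the sample channel alone was 47.9-fold. Ccr10, a receptor for skin and mucosal chemokines, was 40.1-fold higher. In the other direction, Cysltr2, a cysteinyl leukotriene receptor, was 8.27-fold lower and Il6 was 8.09-fold lower. Of 25347 genes tested, 1908 passed an adjusted p of 0.05 in limma, 833 higher and 1075 lower in the knockout. Of these, 202 were at least 2-fold higher and 183 at least 2-fold lower. The groups did not overlap in 1905 of the 1908 called genes. Over all tested genes they did not overlap in 18.3%, where chance gives 5.71%. With slide as a fixed block 478 genes were called, 233 higher and 245 lower, and with a minimum log2 change of 0.5 the count was 210. Of 106 genes named by the rules given with the methods and called, 41 missed the threshold with slide as a block. All 41 kept their sign, which the lack of overlap between the groups largely fixed. Among them were Lta, Plac8, Prss23, Gata3, Bhlhe40, Batf, Areg, Sox4, Ahr, Cd2, Lck, Sh2d1a, Xcl1, Ctsw, Itgb3, Tnfsf4, Chac1, Atf4, Asns, Aen, Zmat3, Perp, Pmaip1, Cdkn2c, Cdkn1b, Rrm1, Kif20a, Isg15, Usp18, Fosl2, Ndufa4, Mycn, Bid, Cd74, Srgn, Cpa3, Hdc, Hba-a1 and Zfp326. Leaving out wild-type array 4 or knockout array 2 gave 1268 and 1262 calls. Without both wild-type array 4 and knockout array 3, the arrays in doubt for their background or scanner quality result, 1137 genes were called, 483 higher and 654 lower. With median centring in place of loess, 55.5% of 1614 calls were higher, against 43.7% of the calls reported here.

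Among the 12 largest rises, the others were Urah (22.5-fold), an enzyme of urate breakdown, Gda (17.5-fold), a guanine deaminase, Cd163l1 (16.3-fold), a scavenger receptor family member found on gamma-delta T cells, Tgfbr3 (14.2-fold), a TGF-beta co-receptor, Fat1 (10.8-fold), an atypical cadherin, Enpp2 (9.72-fold), the enzyme autotaxin, Hoatz (8.49-fold) and Lta (7.47-fold), the cytokine lymphotoxin alpha. Rnf144a, a ubiquitin ligase, was well above background on no wild-type array and on all 3 knockout arrays. It was at least 22.3-fold higher in the sample channel and 14.5-fold higher in the log ratio (limma adjusted p = 4.29e-07 for the log ratio). Hoatz was above background on 1 of the 4 wild-type arrays. Second probes gave smaller differences for Gda (2.55 against 4.13) and Urah (3.65 against 4.49). The Lta call had an adjusted p of 0.042 and was lost with slide as a block (0.36), where the log2 difference was 1.78 against 2.90. It was also lost on leaving out wild-type array 2 or 4 or any knockout array, with an adjusted p of at most 0.112. Wild-type values of Lta varied widely, at 3.58 ± 1.66 (SD, n = 4).

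The other large falls were in Plac8 (6.85-fold), Tmem119 (6.51-fold), Prss23 (6.01-fold), Egln3 (5.91-fold), a prolyl hydroxylase of the hypoxia pathway, Scd1 (5.79-fold), which desaturates fatty acids, and Ero1a (5.53-fold), which forms disulfide bonds in the endoplasmic reticulum. Prxl2a (4.65-fold), Trib3 (4.63-fold), a stress-induced pseudokinase, Slc38a5 (4.47-fold), an amino acid transporter, and Loxl2 (4.4-fold), a lysyl oxidase, completed the 12. Other probes gave smaller falls for Plac8 (-1.40 against -2.78) and Loxl2 (-1.46 and -1.08 against -2.14). Leaving out knockout array 2 ended the Prss23 call (adjusted p = 0.0624).

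**Figure D1:**
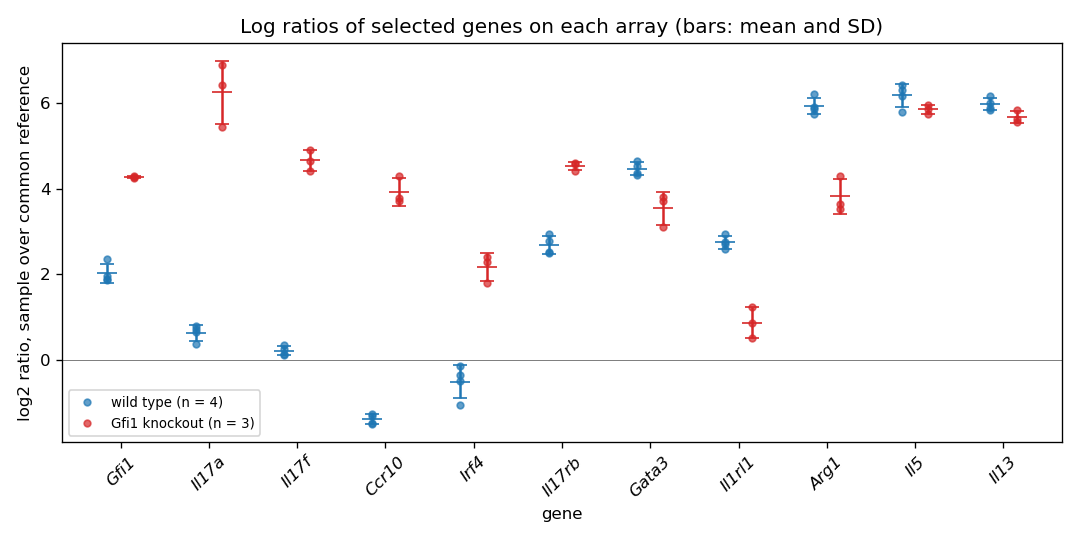
Log2 ratio of sample over common reference (vertical axis) for selected genes (horizontal axis) on each of the 4 wild-type (blue) and 3 Gfi1 knockout (red) arrays. Points are arrays and bars are means with SD. Il17a lies at 6.26 ± 0.73 on knockout and 0.64 ± 0.18 on wild-type arrays, while Il5 and Il13 overlap or lie close together.

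Transcripts of the type 2 programme changed in both directions. Il5 and Il13, the main ILC2 cytokines, did not pass the test, with log2 differences of -0.33 (adjusted p = 0.247) and -0.30 (adjusted p = 0.14). Il9 differed by 0.54 (adjusted p = 0.575). Of 16 tested type 2 cytokines and effectors, 6 fell and 2 rose (2 and 8 adjusted over the list alone, higher and lower). The list went down in camera (adjusted p = 0.0109), with adjusted p = 0.119 with an estimated correlation. Arg1, the arginase of type 2 immunity, fell 4.33-fold and the neuropeptide gene Calca fell by 0.68 on the log2 scale, or 8.39-fold and 3.67-fold in the sample channel alone, since their reference signals also differed (a second Calca probe fell by 1.75), whereas Il10, an inhibitory cytokine, rose 3.41-fold. Il6 was among the other falls, with Bmp7 and Lif, and Il3 was the other rise, these last 3 chosen after their values were seen. Areg, a tissue-repair growth factor, fell by 0.42, a call lost with slide as a block (adjusted p = 0.242) and in 6 of the 7 fits that left out an array. The list's camera call was also lost with the scanner's own log ratio (adjusted p = 0.062).

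The lists of ILC2 regulators and receptors did not pass camera, and members of both moved in both directions. Gata3, the master regulator of type 2 lymphocytes, fell 1.9-fold (adjusted p = 0.0101), and its difference was -0.82 within slide 1 and -0.87 within slide 2. With slide as a block the adjusted p of Gata3 was 0.138. Of 19 tested ILC2 transcription factors, 4 fell and 2 rose (9 and 2 adjusted over the list alone), and the camera adjusted p was 0.0913, while fry's directional test called the list down (adjusted p = 0.0167). Irf4 rose 6.43-fold, while Bhlhe40 fell 1.86-fold and Batf fell 1.39-fold, the last 2 not called with slide as a block (adjusted p = 0.0657 and 0.1). Maf (0.69) and Runx3 (-0.40), chosen after their values were seen, made up the other rise and fall. Tcf7, Id2, Rora and Bcl11b were not called, at log2 differences of 0.47, 0.03, -0.25 and 0.16. A second probe of Tcf7 had the opposite sign, at -0.06. Among 28 tested ILC2 surface receptors, 5 rose and 4 fell (7 and 10 adjusted over the list alone), and the median difference of -0.21 and the mean of 0.05 had opposite signs (camera adjusted p = 0.359). Receptors for 2 of the cytokines that activate ILC2s moved apart: Il1rl1, the IL-33 receptor, fell 3.7-fold (adjusted p = 2e-04), and Il17rb, a subunit of the IL-25 receptor, rose 3.6-fold (adjusted p = 4.71e-05). Other probes of both genes gave smaller changes on the log2 scale, -0.76 and -1.14 for Il1rl1 and 0.48 for Il17rb. Ptgdr2, the prostaglandin D2 receptor, rose 6.05-fold and was above background on 2 of the 4 wild-type arrays, and Ctla4 rose 3.29-fold. Chosen after their values were seen, the other rises were Il18r1 and Tnfsf11 and the other falls Crlf2, Ly6a and Il2rb. The sort markers Icos, Il7r and Kit, with Klrg1, were not called, at differences of -0.11, -0.23, 0.62 and -0.30.

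Genes of type 17 lymphocytes and of ILC3s rose as a group: 12 of 23 tested members rose and 1 fell, with a median difference of 0.65 (14 and 1 adjusted over the list alone). Camera gave an adjusted p of 2.92e-09 with the preset correlation, and the adjusted p was 0.0608 with an estimated correlation. Blk, a kinase above background on 2 wild-type arrays, rose 2.79-fold and Sox4, a transcription factor, 1.71-fold. A second Sox4 probe stood at 0.27 and was not called (adjusted p over probes 0.149). Ahr, a factor that type 17 cells and ILC3s use, fell by 0.78. Il22, another ILC3 cytokine, was not called (0.30, adjusted p = 0.493). The list median was 0.31 within slide 1 and 0.88 within slide 2, and camera with slide as a block gave adjusted p = 1.53e-09, although the members called fell from 12 higher and 1 lower to 4 higher and 0 lower with that block. The sign of both medians was largely fixed by the lack of overlap between the groups in the called members.

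Markers of other lymphocytes were partly higher on the same arrays. Of 18 tested T cell markers, 3 rose and none fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.00798), with a median difference of 0.14. The adjusted p was 0.181 with an estimated correlation. Cd2, above background on 2 of the 4 wild-type arrays, rose 2.89-fold, Lck, the kinase of T cell receptor signalling, 1.68-fold and Sh2d1a, above background on no wild-type array, at least 1.6-fold in the sample channel (1.51-fold in the log ratio). A second Cd2 probe stood at 0.27 and was not called (adjusted p over probes 0.0993). With slide as a block none of the 18 markers was called. Cd5 was not called, at 0.50. Leaving out an array ended the Lck call in 5 of 7 fits. Among 26 tested NK and type 1 genes 5 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.00739), with adjusted p = 0.0936 with an estimated correlation. Nkg7, a cytotoxic granule gene, rose 2.52-fold, Ctsw 1.69-fold and Xcl1, a chemokine above background on no wild-type array, at least 2.4-fold in the sample channel (2.05-fold in the log ratio), while Stat4, the IL-12 signal transducer, fell 1.8-fold. The other members called, chosen after their values were seen, were Gzme and Cxcr3 (higher) and Il18rap (lower). Tbx21 and Ifng were not called, at 0.82 (adjusted p = 0.0805) and 0.29 (adjusted p = 0.769).

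Chemokine receptors and homing genes also rose: 9 of 29 tested members rose and 1 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.000185), with adjusted p = 0.0608 with an estimated correlation. Besides Ccr10, Ccr7, which guides cells to lymph nodes, rose 6.02-fold and S1pr1, which guides their exit, 3.69-fold. Itgb3, an integrin chain, fell 1.54-fold. Among 20 co-receptor and checkpoint genes 6 rose and 1 fell (6 and 2 adjusted over the list alone), among them Havcr2 (2.09-fold) and Tnfsf4 (2.06-fold). Btla rose 2-fold and was above background on 2 of the 4 wild-type arrays. Pdcd1lg2, chosen after its value was seen, fell by 0.49 on the log2 scale. The camera adjusted p for this list was 0.0472, and 0.181 as an adjusted p with an estimated correlation. It missed the threshold under many settings, among them the scanner's own log ratio (0.076), the sample channel alone (0.331), the sex covariate (0.0584), without both doubted arrays (0.0563) and on leaving out wild-type array 1 or 2 or knockout array 1 or 3, with an adjusted p of at most 0.0853.

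Genes of glucose and cholesterol metabolism were lower on the arrays labelled knockout. Of 23 glycolysis genes 14 fell and none rose (17 and 0 adjusted over the list alone), with a median difference of -0.71 (camera adjusted p = 1.44e-14). The adjusted p was 0.0608 with an estimated correlation. The glucose transporters Slc2a3 and Slc2a1 fell 2.57-fold and 2.41-fold, the regulatory kinase Pdk1 fell 1.99-fold and Pfkfb3 fell 1.85-fold, although a second Pfkfb3 probe stood at 0.04. Cholesterol biosynthesis genes fell in 15 of 24 cases and rose in none (21 and 0 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 5.25e-17), and the adjusted p was again 0.0608 with an estimated correlation. Sc5d fell 1.88-fold, Srebf2, which drives the pathway, 1.82-fold and Fdps 1.7-fold. A second Srebf2 probe stood at -0.20 and was not called (adjusted p over probes 0.203). Within slides 1 and 2 the medians were -0.56 and -0.58 for glycolysis and -0.50 and -0.54 for cholesterol synthesis, and camera with slide as a block gave adjusted p = 4.87e-14 and 9.19e-17. With most members called lower, and groups that hardly overlapped among called genes, the signs of these medians were largely fixed. With that block 4 glycolysis and 4 cholesterol synthesis genes were called lower.

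Hypoxia and stress markers moved with them, 8 falling and 1 rising of 19 tested (9 and 3 adjusted over the list alone; camera adjusted p = 0.000956), with adjusted p = 0.181 with an estimated correlation. Besides Egln3, Ankrd37 fell 3.23-fold and Vegfa 3.13-fold. Gclm, a glutathione synthesis gene, rose 1.72-fold. The heat-shock members were not called. Unfolded protein response genes fell in 4 of 22 cases (5 adjusted over the list alone; camera adjusted p = 0.000987), with adjusted p = 0.181 with an estimated correlation. The 4 were Trib3, Chac1 (4.4-fold), Atf4 (1.87-fold) and Asns (1.74-fold), genes of the amino acid response, and the chaperone genes of the list were not called. Leaving out wild-type array 1, 2 or 4 or knockout array 2 ended the Atf4 call, and leaving out knockout array 2 ended that of Asns.

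**Figure D2:**
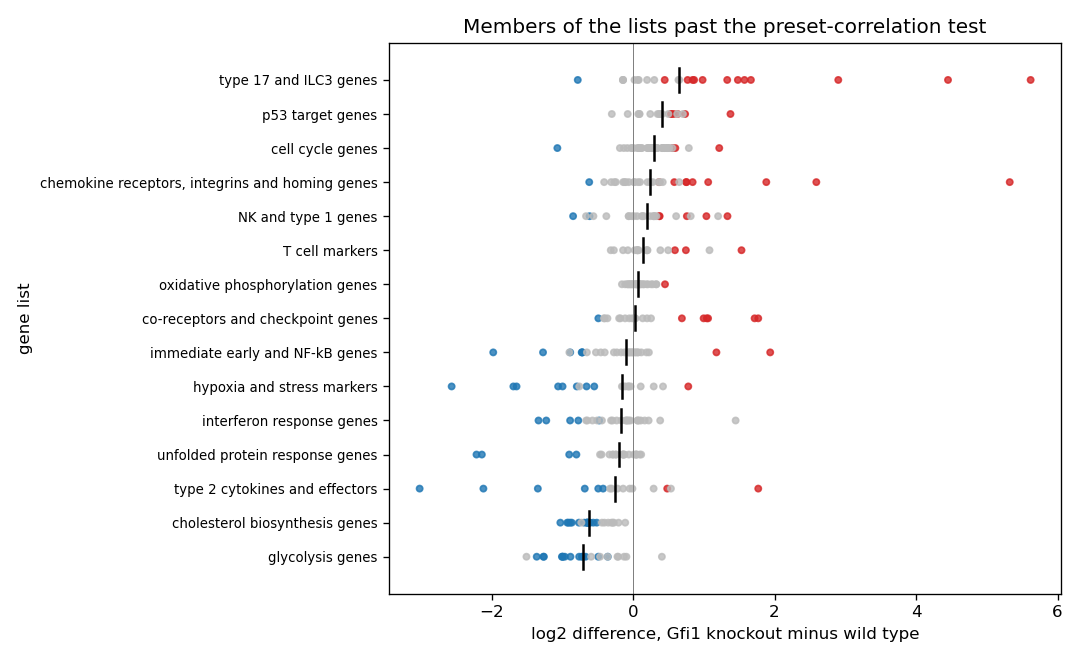
Log2 difference, knockout minus wild type (horizontal axis), of every tested member of the 15 gene lists (vertical axis) that passed camera with the preset correlation. Red and blue points are genes called higher and lower, grey points were not called and black bars are list medians, from -0.71 for glycolysis to 0.65 for type 17 and ILC3 genes.

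Camera also called 5 further lists. Among 19 p53 target genes 6 rose and none fell (11 and 1 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 3.32e-07), and the adjusted p was 0.0608 with an estimated correlation. Plk2 rose 2.6-fold, Aen 1.67-fold, Zmat3 1.49-fold and Perp 1.55-fold. With slide as a block the p53 list kept its median (0.41), but 1 member was called. Of 41 cell cycle genes 3 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 4.32e-07), with adjusted p = 0.255 with an estimated correlation. Cdkn2c and Cdkn1b, both inhibitors of the cycle, moved in opposite directions, up 2.33-fold and down 2.1-fold. The other rises, Rrm1 (1.51-fold) and Kif20a (1.47-fold), were each lost in 5 of the 7 fits that left out an array. The cell cycle median was 0.30 over all arrays and 0.37 within slide 1 but -0.013 within slide 2, so the shift did not hold within both slides. With slide as a block the median was 0.17, with 34 of 41 members above 0, and camera still called the list (adjusted p = 0.000543). The fall of Cdkn1b was lost on leaving out any wild-type array or knockout array 2. Interferon response genes fell in 5 of 27 cases (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00739), with adjusted p = 0.481 with an estimated correlation. Oas1a fell 2.52-fold, Isg15 1.85-fold, Ddx58 1.71-fold and Usp18 1.39-fold, with Ifih1, chosen after its value was seen, 2.34-fold lower. That list missed the threshold without wild-type array 4 (adjusted p = 0.0692) and without both doubted arrays (adjusted p = 0.257). Immediate early and NF-kB genes fell in 6 of 30 cases and rose in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0125), with adjusted p = 0.162 with an estimated correlation. Dusp6, a MAP kinase phosphatase, fell 3.93-fold, Ier3 2.42-fold and Fosl2 1.64-fold (a second Fosl2 probe, at -0.13, was not called), while Tnf rose 3.83-fold and Dusp2, chosen after its value was seen, rose by 1.18 on the log2 scale. Leaving out wild-type array 1 gave adjusted p = 0.0688 for this list. Oxidative phosphorylation genes had a median of 0.07, with Ndufa4 alone of 29 called (1.37-fold higher, a call lost in 6 of the 7 fits that left out an array; 0 adjusted over the list alone; camera adjusted p = 0.0472). The adjusted p was 0.255 with an estimated correlation, the median was -0.012 within slide 2, and the call was lost with slide as a block (0.179) and with the sex covariate (0.0967), while 5 of the 7 fits that left out an array missed the threshold. None of the 29 lists passed with an estimated correlation in camera, where the lowest adjusted p was 0.0608.

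The remaining lists did not pass camera as fitted without a block. With slide as a block the mast cell and basophil list passed downward (adjusted p = 0.0368) and the stem and progenitor list upward (adjusted p = 0.0459). Both also passed fry's directional test (adjusted p = 0.00194 and 0.0234), as did the lists of genes repressed by Gfi1 (0.00736), apoptosis (0.00148) and Notch and TGF-beta (0.0386), all upward. The list of genes repressed by Gfi1 holds the altered gene Gfi1 itself, so its rise is partly built in. The median difference of that list was 0.00096. Fry's directional test did not call the cell cycle (adjusted p = 0.0886), interferon response (0.126) and oxidative phosphorylation (0.0886) lists, which camera called. Leaving out an array brought 2 lists past camera, macrophage and dendritic cell markers without wild-type array 1 (adjusted p = 0.0308) and ribosomal protein genes without knockout array 1 (adjusted p = 0.0262), both upward. Of 24 tested genes known as repressed by Gfi1 in blood cells, 4 rose, Gfi1 itself, Meis1 (2.96-fold), Id3 (2.7-fold) and Id1 (2.23-fold), and 2 fell, Irf8 and Stat3, chosen after their values were seen (camera adjusted p = 0.16). Stem and progenitor genes rose in 5 of 19 cases and fell in 1 (camera adjusted p = 0.144), with Mycn 2.96-fold and Procr 1.9-fold higher and Hlf, chosen after its value was seen, lower. Among 25 Notch and TGF-beta pathway genes 6 rose and 5 fell (camera adjusted p = 0.185). Hes1 fell 2.23-fold and Rbpj, the Notch effector, 2.36-fold, with Notch2, Tgfbr2 and Tgfb3, chosen after their values were seen, also lower. The 6 rises were Tgfbr3, Id3, Id1 and, chosen after their values were seen, Jag1 (0.64), Hey1 (0.51) and Tgif1 (0.40). Jag1 was above background on 1 of the 4 wild-type arrays. No tested marker of B cells (13) or neutrophils (13) was called, nor any of 31 ribosomal protein genes (camera adjusted p = 0.68, 0.566 and 0.356). Among 19 macrophage and dendritic cell markers H2-Ab1 fell 2.53-fold (6.43-fold in the sample channel alone) while Ctss rose 1.98-fold and Cd74 1.7-fold (camera adjusted p = 0.0799). Mast cell and basophil markers fell in 3 of 13 cases, Srgn (1.75-fold), Cpa3 and Hdc, the last 2 lost in 6 and 4 of the 7 fits that left out an array (camera adjusted p = 0.0799). The adjusted p was 0.193 for 17 erythroid and megakaryocyte genes, of which Hba-a1 fell 1.81-fold, and 0.203 for 22 apoptosis and survival genes, of which 3 rose, among them Bid and Pmaip1, both calls lost in 6 of the 7 fits that left out an array.

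The sex-linked genes showed that both groups held 2 kinds of pool. Eif2s3y, on the Y chromosome, was high on 2 of 4 wild-type and 2 of 3 knockout arrays, and Xist was high on the other 2 wild-type arrays and the other knockout array. The pattern followed the replicate number: arrays 1 and 2 of both groups were high in Eif2s3y, and the others in Xist. None of the 4 tested sex-linked genes was called (camera adjusted p = 0.566).

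Calls were also counted near Gfi1 on its chromosome, where a knock-in can carry flanking sequence of the strain it was made in. Tgfbr3, which lies near Gfi1, rose, Lrrc8d rose 1.56-fold, Zfp326 rose 1.43-fold (a call lost in 3 of the 7 fits that left out an array) and Dipk1a fell 2.05-fold among the 19 tested genes of a fixed list of neighbours (3 rose and 1 fell; camera adjusted p = 0.203). Within 10 Mb, 27 of 175 tested protein-coding genes were called (15.4%), 14 higher and 13 lower, against 8.94% of 16092 outside. Plac8 and Tmem119, among the largest falls, also lie within this window, as do Gpat3 (7.16-fold higher) and Crlf2 (1.92-fold lower), these last 2 chosen after their values were seen. The odds ratio was 1.86 (95% interval 1.18 to 2.82, two-sided Fisher's exact p = 0.00506). It was 1.88 within 20 Mb (exact p = 7e-05), 1.39 within 5 Mb (95% interval 0.666 to 2.63, exact p = 0.273) and 1.58 against the same chromosome alone (exact p = 0.0638). Genes are not independent of each other, so these p-values describe the arrays and not separate experiments.

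The slides held both groups unevenly, with 1 array of each group on slide 1, 1 wild-type and 2 knockout arrays on slide 2, and 2 wild-type arrays on slide 3. Deviations from the group means correlated at -0.07 on average between arrays of different groups on the same slide (3 pairs) and at 0.02 between those on different slides (9 pairs), a difference of -0.09 that was smaller than the spread of 0.18 among the latter.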

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

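The tests of windows along the genome and of other splits of the arrays were set before their results were seen. The tests of T cells, slides, normalization, culture and probe mismatch were chosen after the results they bear on.

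Of 151 values examined in the 4 wild-type arrays, 10 had one array far from the other 3, where chance gives about 7.55. Wild-type array 4 stood apart for Rora (3.45), Lck (-1.94), Cd74 (-1.76), Slamf1 (-0.29) and S1pr1 (-0.57). Wild-type array 3 did so for Il6 (4.84) and Bid (-1.34), array 1 for Aen (0.14) and Srebf2 (1.19), and array 2 for Tnfsf4 (0.21).

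In the reference channel, which holds the same RNA on every array, 10 genes were called between the groups, and none in any of the 34 other splits of the arrays. At an unadjusted limma p under 0.05 the real split held 1469 genes in that channel. The arrays of slide 2 set against the rest held 2770, and wild-type arrays 2 and 3 with knockout array 1 held 2930. Of the genes called in the real split, some details follow. Of the 10, 9 were also called in the log ratio and 5 had the same sign there. Il17f differed by 1.13, Calca by -1.19, H2-Ab1 by -1.34 and Arg1 by -0.95 in that channel, all in the direction of the log ratio. Nme2, chosen after its value was seen, differed by -1.34 there, and by 1.11 in the log ratio but -0.24 in the sample channel alone. The log ratios of Il17f, Arg1, Calca and H2-Ab1 therefore do not rest on an equal reference. They were smaller than the change in the sample channel, which was 47.9-fold for Il17f, 8.39-fold for Arg1, 3.67-fold for Calca and 6.43-fold for H2-Ab1. The cause was not tested, so it cannot be told whether the log ratio or the sample channel lies nearer the true change.

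Of the 35 splits of the 7 arrays into 3 and 4, 1 called as many genes as the real split, namely the real one itself. It called 1908 genes and the highest other split 4. A share of 1 in 35 is the smallest these splits can give, so chance is argued against but not excluded. The other splits also mix the groups, so a real difference widens their spread and lowers their counts. For gene lists the number of splits with as many lists past the threshold was also 1, the real one, with 15 lists against 12 in the highest other split. Chance is argued against by this count too, within the same limit. That other split set wild-type arrays 2, 3 and 4 against the rest. It kept the 3 knockout arrays together and so still held part of the real contrast. Its 12 lists therefore do not show what camera calls under an unrelated grouping. Splits with 2 knockout arrays in the smaller group brought 3 to 8 lists past the threshold, but these too held part of the real contrast. Splits with 1 knockout array there were closer to balanced and brought 0 to 5. Camera with a preset correlation thus still called some lists in some of these more balanced groupings.

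Type 17 genes were higher on arrays labelled knockout. The list stayed up with slide as a block (camera adjusted p = 1.53e-09 with the preset correlation). Its median was above 0 in both slides holding both groups. With 12 of 23 members called higher, and groups that hardly overlapped among called genes, these signs were largely fixed. Fewer members were called with the block. Slide differences are thus argued against only by the size of that camera result, which relied on the preset correlation, and are not excluded. A contribution of IL-17-producing T cells stays open, although the sort excluded cells with lineage markers. The 75th percentile of the differences of 18 T cell markers was 0.47, with Cd3d at 1.08, Cd3e at 0.39, Cd3g at -0.07 and Lat at 0.07, none of them called. Since 16 of the 18 were above background on all 4 wild-type arrays, a small share of T cells could be hidden. A change of the ILC2s themselves with genotype is another open explanation.

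Glycolysis, cholesterol and hypoxia genes were lower together. The loess step is argued against as the source, since all 3 lists stayed down with median centring in its place. They also stayed down in the sample channel alone, with a highest camera adjusted p of 0.00528 over both settings. Median centring still uses the ratio, and the sample channel was taken after loess and Aquantile. A part of the reference in the result is therefore not excluded. Culture conditions that may have differed between groups, such as cell density or oxygen, cannot be told apart from genotype. The labels give no culture condition that varies within a group. Every wild-type array lay above every knockout array, by at least 0.47 in the median of the lists' 65 members. The lists were chosen because they were lower in the knockout, so this gap decides nothing. Genotype therefore stays one of the open explanations.

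Calls were more frequent near Gfi1. Probe mismatches from flanking sequence would lower signals. They do not account for the higher calls, which were in excess (8% against 3.94% outside, exact p = 0.0169). Lower calls made up 7.43% against 5.0% outside (exact p = 0.16). Ordinary clustering of called genes is argued against by a narrow margin: 3.18% of 15023 overlapping windows elsewhere held as high a share of calls. Because they overlap, these windows are not separate regions. Against the same chromosome alone the odds ratio was 1.58 (exact p = 0.0638), and within 20 Mb it was 1.88, so the excess was not confined to 10 Mb. Clustering is therefore not excluded. Within 5 Mb the odds ratio was 1.39, with a 95% interval of 0.666 to 2.63 that holds both no excess and the 10 Mb value. Regulatory differences carried by flanking sequence, a possible explanation also for Tgfbr3, Plac8, Tmem119 and Gpat3 within 10 Mb, and the loss of Gfi1 both stay open.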

How the results depend on the processing

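Flag handling, the sex covariate and the exclusion of the arrays in doubt were added after seeing the data, and the other settings were fixed beforehand. Of 1908 calls, each had the same sign under every setting except for 1 with median centring, 1 with the mean of a gene's probes, 11 in the sample channel alone and 1 within slide 1, among the calls present there. The groups did not overlap in 1905 of the calls. Signs within slides, with a fixed slide block and with an array left out were therefore fixed for these. That agreement adds no support. The count of calls fell to 478 with slide as a fixed block (233 higher, 245 lower), which leaves fewer degrees of freedom, rose to 2122 with slide as a random block (consensus correlation -0.135), and fell to 210 with a minimum change (116 higher, 94 lower). Without the arrays in doubt it was 1137 (483 and 654). Leaving out single arrays gave 1262 to 1897 calls, 528 to 881 higher and 734 to 1016 lower, the low counts coming without wild-type array 4 (1268) and knockout array 2 (1262). Flag handling moved the count to 1780 (755 and 1025) or 1824 (797 and 1027), and the sex covariate to 2358. With the replicate block it was 1081 (485 and 596). Same-numbered arrays' deviations correlated at 0.04, 0.24 and 0.02, and 1 of 3 knockout arrays correlated best with its own number. These values show no clear pairing. They cannot exclude one, since arrays of equal number also had the same pattern of sex-linked genes. The Gfi1 difference stayed between 2.03 and 2.43 under all settings. Of 106 named called genes, 65 were called with slide as a block, 88 with the replicate block and 91 in every fit leaving out an array. None of the 106 reversed, which the lack of overlap between the groups largely fixed. Lists past the threshold numbered 15, and 13 to 16 under settings of normalization, model or arrays, but 0 with an estimated correlation, 18 with fry's directional and 24 with its mixed test. Within slide 2 the median of cell cycle genes turned to -0.0128 and that of oxidative phosphorylation genes to -0.0125. The neighbourhood odds ratio was 1.39 within 5 Mb, 1.58 against the same chromosome and 1.88 within 20 Mb, and the cause was not tested. The slide effect was -0.05 in the series value table. Scan could not be run apart from slide. Signal over background limits the genes near the floor: 32582 genes could be tested without a filter and 21693 with all 7 arrays above background, with 1859 and 1779 calls.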

Other observations

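Further called genes, chosen after their values were seen, are given as single values. Gpat3, which starts triglyceride synthesis, rose 7.16-fold and Fabp4, a fatty acid carrier, 6.2-fold, while the desaturase Scd2 fell 3.88-fold and Mgll, a monoglyceride lipase, 2.96-fold. Fut7 and Gcnt1, which build selectin ligands, rose 6.5-fold and 4.13-fold. Alox5, which makes leukotrienes, fell 4.36-fold on the same arrays as the leukotriene receptor Cysltr2. Hilpda and P4ha2, known hypoxia-induced genes, fell 3.26-fold and 3.17-fold.

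Also chosen after their values were seen, the transcription factor genes Snai2 and Myb rose 6.96-fold and 2.74-fold. Il31, a type 2 cytokine, rose 2.72-fold, while Irf8, a partner of Irf4 in other lymphocytes, fell 2.54-fold. Each passed the adjusted threshold with all 7 arrays, and Il31 was above background on 2 of the 4 wild-type arrays.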
